A study of Mus musculus with 2 samples.

How the data were processed

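Trimethylation of histone H3 at lysine 9 (H3K9me3), a mark of heterochromatin, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole intestine of mouse embryos at embryonic day 16.5, strain B6NCrl, with both sexes pooled. The design holds 1 group with 2 biological replicates and no second tissue, age or treatment. Replicate 2 was pooled from 41 embryos per the labels; the labels call replicate 1 pooled without giving a number. The replicates are named as biological replicates per the labels.

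The authors deposited 4 peak lists on the mm10 build, in narrowPeak format per the file headers. One list came from each replicate, one from both replicates pooled, and one, named as replicated, was derived from the pooled list and both replicates' lists per the deposited file descriptions. The rule by which peaks entered the replicated list, the aligner, the peak caller and their versions are not given in the sources used here. Each peak carries a deposited signal value, an enrichment measure whose scale is not stated, and 2 deposited significance columns, the −log10 of a p-value and the −log10 of a q-value. Every signal value and significance below is the authors' own value for that peak. The values were used only to describe, rank or filter peaks within a list, and to correlate paired peaks between the replicates. All 4 lists begin at a −log10 p of about 2, so weak peaks are present in each.

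The lists hold no read totals, so the sequencing depth of either library is unknown and no confidence interval could be based on it. A longer list can reflect deeper sequencing, higher enrichment or a different background, which peak lists alone cannot separate. Reads from repeated sequence may have been filtered or placed at random before peaks were called. Large repeat arrays are missing from the assembly, so the marked share of repeats is understated. The narrowPeak format also divides broad H3K9me3 domains into many short intervals, and a domain therefore appears as a run of peaks.

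Peak positions were compared with the GRCm38 reference sequence, whose chromosome lengths fit mm10, and with the GENCODE annotation of that build. Positions are given 1-based. The analysis used peaks on the assembled autosomes, X and Y; peaks on unplaced and unlocalised scaffolds were counted separately. The annotation gave 21938 protein coding genes, 10155 long noncoding RNA genes and 362 immunoglobulin and T cell receptor V segments. The V segments were added to the background after the plan was fixed, since a planned gene list consists of them.

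Chance was set by random circular relocation. Each chromosome's peaks were shifted together by one random offset in gap-free coordinates, which keeps their number, widths, spacing and clustering, and the overlap was counted again in 10000 relocations. Relocation keeps neither the GC content of the sequence under a peak nor how well reads can be placed there. The two-sided p from these relocations, called a permutation p here, is the doubled smaller tail with the observed value counted, and the smallest p these relocations can give is 0.0002. Values given as mean ± SD of relocations describe this chance distribution, not a spread between animals. Adjusted p values are Benjamini-Hochberg over the 23 gene lists, or over the classes of genomic location. Where peaks of the 2 replicates were compared, an overlap of at least 1 bp counted as shared. Genes counted as marked when at least 1 bp of a replicated peak lay in the gene body or, in a separate test, within 1 kb of the gene start. Peak midpoints within 1 kb of a gene start were assigned to promoters, then to exons, introns or intergenic sequence in that order.

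The 23 gene lists were fixed before the data were examined. They cover zinc finger, olfactory receptor, vomeronasal receptor, clustered protocadherin, Hox, V segment, cytochrome P450, keratin, serpin, defensin, histone, imprinted, germline, 2-cell stage, intestinal epithelium, gut mesenchyme, enteric nervous system, endothelial, blood, liver and pancreas, other organ, housekeeping and H3K9 methylation machinery genes. The zinc finger list was drawn from gene symbols and so includes zinc finger genes without a KRAB domain. C2H2 zinc finger arrays were also located in the genome sequence itself, as runs of at least 4 in-frame linker motifs with at most 2 kb between neighbours, which gave 514 arrays. For last exons, the transcript with the longest coding sequence was used in genes with more than 1 exon, and last exons were set against gene starts by a two-sided exact McNemar test. Peaks of the replicated list closer than 10 kb were joined into domains.

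Genes were named by a rule fixed before the data were examined. It takes the 10 genes with most replicated-peak bases in the gene body, the 10 genes with the highest signal value within 1 kb of the start, up to 4 members of each gene list by peak bases, and every imprinted gene with a peak. A named gene also had a peak in each replicate's own list at that gene or window, unless the text says which replicate lacked one. The same rule was applied to members with a marked start, by signal value, after the data were seen. In the germline list every member with a marked start was named.

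The relocation test was first tested on simulated data made by relocating the replicated list. With no planted effect, 2.57% of 2300 list tests over 100 simulated lists had an unadjusted p under 0.05. The simulated lists were made by the same relocation that the test uses, so a low share was set in advance. It cannot show false calls that come from GC content or from how well reads can be placed. With peaks planted at 12 of the germline genes the list was called in 90% of 50 simulations, and with peaks planted at 6 of them in 16%. Smaller shifts in a list of that size would therefore often be missed.

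Alternatives covered each replicate's own list, the pooled list, stricter thresholds (q at or below 0.01, or signal value at or above the list median), other overlap rules and windows, a protein coding background, Fisher's exact test, other zinc finger array definitions and other joining distances. The planned rule of a peak lying mostly inside a gene was run as the peak midpoint inside the gene. After seeing the data, 2 alternatives were added: leaving out 73 peaks with a signal value under 3 and a −log10 p of at least 10, and keeping only replicated peaks met by both replicates' own lists. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.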

Results

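The data describe where H3K9me3 lay in the intestine of embryonic day 16.5 mice. Each of the 2 biological replicates was a pool of intestine, and one peak list was available per replicate. Replicate 1 had 40722 peaks covering 10.3 Mb and replicate 2 had 10775 peaks covering 2.75 Mb. The pooled list held 31243 peaks over 9.72 Mb and the replicated list 8279 peaks over 3.78 Mb. Median peak widths were 216 bp in replicate 1, 214 bp in replicate 2 and 379 bp in the replicated list. The share of peaks with a q-value at or below 0.05 was 27.2% in replicate 1, 16.5% in replicate 2, 53.3% in the pooled list and 88.6% in the replicated list. Since the labels name a single group, the comparisons below are between the replicates, and between the peaks and chance placement on the genome.

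The replicates marked overlapping parts of the genome far more often than chance, but most peaks of the longer list had no partner. Of the 10574 replicate 2 peaks on assembled chromosomes, 4282 (40.5%) overlapped a replicate 1 peak, against 0.837% ± 0.101 (mean ± SD of relocations), a ratio of 48.4 (two-sided permutation p = 0.0002, the smallest the relocations can give). In the other direction, 4266 of 40435 replicate 1 peaks (10.6%) overlapped replicate 2, 48.1 times the relocation mean (permutation p = 0.0002). Peaks shared with the other replicate were wider and had higher signal values. In replicate 1 the median width was 296 bp for shared and 211 bp for unshared peaks, and the median signal value was 3.38 and 3.07. To compare equal numbers, replicate 1 was cut to its 10574 strongest peaks, and every replicate 2 peak on assembled chromosomes was kept. Then 22.8% of replicate 2 peaks and 21.6% of replicate 1 peaks were shared.

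**Figure D1:**
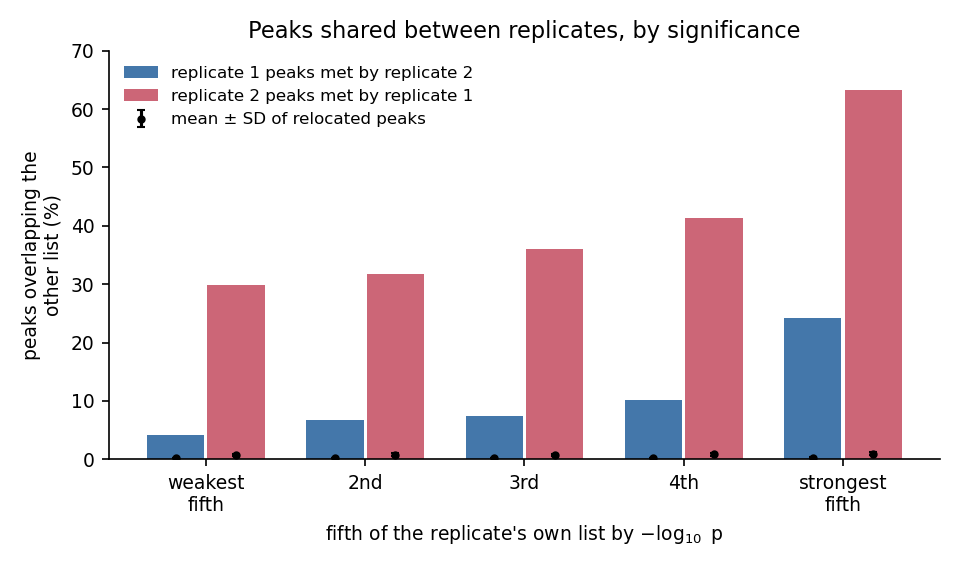
Bars give the percent of each replicate's peaks that overlap the other replicate's list, with the peaks of each list ranked by −log10 p and divided into 5 groups of similar size; black points are the mean ± SD of relocated peaks. The share rises from 4.17% to 24.3% in replicate 1 and from 29.9% to 63.3% in replicate 2.

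Signal values of peaks paired between the replicates were weakly related. Across 4059 best one-to-one pairs on assembled chromosomes Pearson's r was 0.32 and Spearman's rho 0.23. These are correlations across peaks, which are not independent replicates, so no p is given. With the significance column in place of the signal value, Pearson's r was 0.67 and Spearman's rho 0.25.

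Every one of the 8279 replicated peaks, those on scaffolds included, was identical to a peak of the pooled list. Both replicates' own lists had an overlapping peak at 4253 of them (51.4%). Only replicate 1 had one at 2895 (35.0%), only replicate 2 at 777 (9.39%), and neither list had one at 354 (4.28%). The name of the list therefore does not mean that each peak was called in both replicates, and counts from the replicates' own lists are given beside the main groups of genes.

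Replicated peaks were not evenly spread over the chromosomes. The autosomes carried 3.34 peaks per Mb of assembled sequence. Chromosomes 7, 17 and 5, at 5.31, 5.11 and 4.92 peaks per Mb, were the densest, and chromosome 14 was the sparsest autosome at 2.09. The X chromosome had 104 peaks, or 0.636 per Mb, 0.191 of the autosomal density (95% exact binomial interval 0.156 to 0.231, counting error only). The same ratio was 0.270 in replicate 1's own list and 0.444 in that of replicate 2. The Y chromosome had 6 replicated peaks, or 0.0681 per Mb. The embryos were of both sexes, so X and Y were present in fewer copies than autosomes. Whether copy number accounts for the size of the X difference was not tested, and no test across chromosomes was made.

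**Figure D2:**
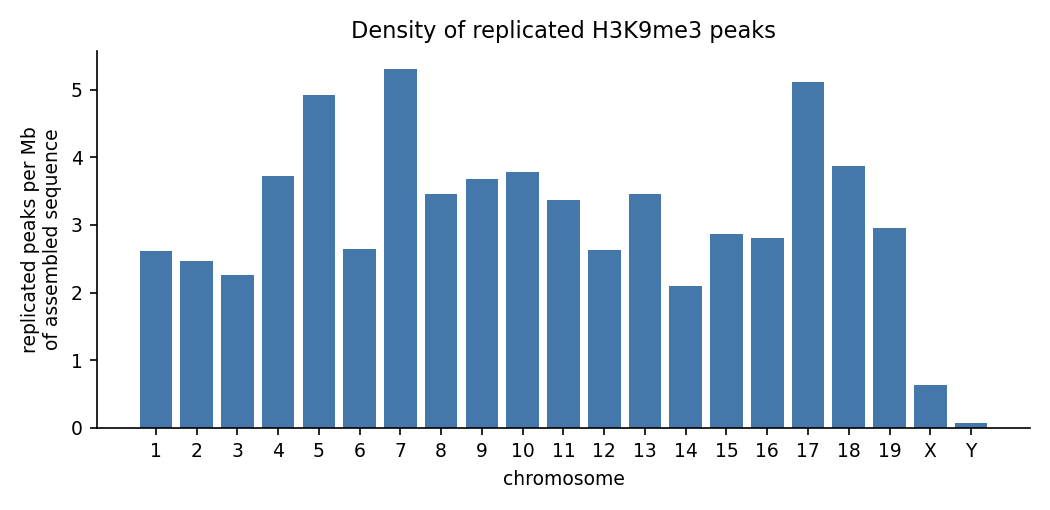
Bars give the number of replicated H3K9me3 peaks per Mb of assembled, gap-free sequence on each mouse chromosome. Autosomes lie between 2.09 (chromosome 14) and 5.31 (chromosome 7), and X is at 0.636.

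Peaks lay in exons and promoters more often than relocated peaks did, and in introns less often. Exons held 7.95% of peak midpoints, against 3.96% ± 0.275 after relocation (adjusted permutation p = 0.0008). Promoters held 3.25%, against 2.40% ± 0.201 (adjusted permutation p = 0.0012), and introns 39.0%, against 42.1% ± 1.14 (adjusted permutation p = 0.0072). Exons held 5.08% (ratio 1.303) and promoters 2.71% (ratio 1.15) in replicate 1's own list, and 7.52% (ratio 1.92) and 3.46% (ratio 1.47) in replicate 2's. Introns did not pass with peaks met by both replicates' own lists (39.6%, adjusted permutation p = 0.081). Intergenic sequence held 49.8%, against 51.6% ± 1.24, which did not pass the threshold (adjusted permutation p = 0.173), while in replicate 1's own list the share lay above relocation and passed (55.4%, against 51.8%, adjusted permutation p = 0.00027). Peak bases were 48.1% GC, against 42.0% ± 0.228, and their CpG content was 0.240 of that expected from base composition, against 0.194 ± 0.00304. Repeats, as soft-masked in the reference, made up 25.99% of peak bases, against 33.7% ± 0.594. All 3 composition values had permutation p = 0.0002, and reads from repeats are the ones most easily lost in alignment. Relocated peaks were not matched on GC content or repeats, so the exon and promoter excess was not told apart from either.

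C2H2 zinc finger genes, which encode a large family of DNA-binding proteins that includes the KRAB repressors, were among the most frequently marked genes. Of 425 such genes, 118 (27.8%) carried a replicated peak in the gene body, against 32.6 ± 6.48 after relocation, a ratio of 3.62 (adjusted permutation p = 0.0023). Replicate 1's own list marked 203 and replicate 2's own list 122, and 106 of the 118 had a peak in both. The genes with most peak bases were Zfp110 on chromosome 7 (12834761 to 12850577), with 13 peaks over 9234 bp, Zfp873 on chromosome 10 (82048123 to 82064745), with 9 peaks over 7294 bp, Zfp763 on chromosome 17 (33016863 to 33033402), with 6 peaks over 6002 bp, and Zfp180 on chromosome 7 (24081924 to 24107713), with 7 peaks over 5910 bp. The ratio to relocation was 1.76 in replicate 1's own list and 3.02 in replicate 2's.

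Within these genes the last exon was marked more often than the start; the rest of the gene body was not tested. Among 419 zinc finger genes with more than 1 exon, 83 had a peak in the last exon, where the finger array is usually encoded, and 12 had one within 1 kb of the start of the transcript used, which can differ from the start of the gene. In 80 genes only the last exon was marked and in 9 only the start (two-sided exact McNemar p = 2.3e-15). This test takes genes as independent, but neighbouring zinc finger genes can lie in 1 run of peaks, so its p may be too small. Relocated peaks met 4.93 ± 2.44 of these last exons and 3.72 ± 2.06 of these starts, so the starts were also above relocation (ratio 3.22, permutation p = 0.0032). The starts did not pass in replicate 1's own list (ratio 1.54, permutation p = 0.089), replicate 2's (ratio 2.14, permutation p = 0.072) or the pooled list (ratio 1.53, permutation p = 0.142). In 20008 other protein coding genes the last exon was marked in 152 and the start in 164, with 140 genes marked only at the last exon and 152 only at the start (exact p = 0.52). Arrays found in the genome sequence without gene names gave a similar picture: 69 of 514 arrays (13.4%) met a replicated peak, against 2.62 ± 1.71 after relocation, a ratio of 26.3 (permutation p = 0.0002). Replicate 1's own list met 106 arrays (ratio 10.2) and 128 last exons (ratio 6.24), and replicate 2's own list 68 arrays (ratio 24.4) and 79 last exons (ratio 13.9).

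Imprinted genes, which are expressed from only one parental allele, had the highest share of marked gene bodies of any list in the replicated peaks. A replicated peak lay in the body of 37 of 55 imprinted genes (67.3%), against 6.91 ± 2.49 after relocation, a ratio of 5.35 (adjusted permutation p = 0.0023). Within 1 kb of the start, 18 were marked, against 0.449 ± 0.705, a ratio of 40.1 (adjusted permutation p = 0.0023), and both replicates' own lists had a peak at all 18 starts. Replicate 1's own list marked 42 bodies (ratio 2.01) and 22 starts (ratio 11.1), and replicate 2's own list 38 bodies (ratio 4.44) and 19 starts (ratio 36.4). Gnas on chromosome 2 (174284320 to 174346744), which encodes a G protein subunit, had the most, with 10 peaks over 7794 bp. Airn, the antisense RNA that silences Igf2r, had 7 peaks over 4881 bp. Its start peak on chromosome 17 (12741118 to 12743226) had a signal value of 5.41, the highest at any start in the fixed imprinted list, and lies inside the Igf2r gene as well. The start peak shared by Peg3 and Usp29 (chromosome 7, 6729083 to 6730710) had a signal value of 4.68, and the one shared by Peg10 and Sgce (chromosome 6, 4747026 to 4748445) a value of 3.71. Start peaks were also found at Nnat (4.93), Cdkn1c (4.89), Slc38a4 (4.63), Peg13 (4.53), Nap1l5 (4.47), Meg3 (4.32), Gnas (4.19), Zrsr1 (3.88), Nespas (3.797), Snurf (3.71), Mkrn3 (3.46), Mcts2 (3.46) and Kcnq1ot1 (3.33), where the number is the highest signal value at the start.

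Several imprinted genes carried a replicated peak only away from the annotated start of the gene. These were Trappc9, Mest, Blcap, Grb10, Commd1, Snrpn, Impact, Igf2r, H13, Kcnq1, Magel2, Plagl1, Herc3, Gpr1, Sfmbt2 and Smoc1, with peaks in both replicates' own lists. Only the outer start of each gene was used, so a peak at an internal start counts as away from it. Some of these peaks were the start peak of another imprinted gene. They lay at Peg13 in Trappc9, Zrsr1 in Commd1, Snurf in Snrpn, Nap1l5 in Herc3 and Airn in Igf2r. The start peaks of Kcnq1ot1 in Kcnq1, Mcts2 in H13 and Nnat in Blcap were of the same kind. Rian and Inpp5f also had a replicated peak in the body, but replicate 2's own list had none there, and Zim1 had none in replicate 1's. Because overlapping genes share peaks, the 37 imprinted bodies were marked by 76 distinct peaks and the 18 starts by 22. Unmarked members of the list included H19, Igf2 and Ndn.

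**Figure D3:**
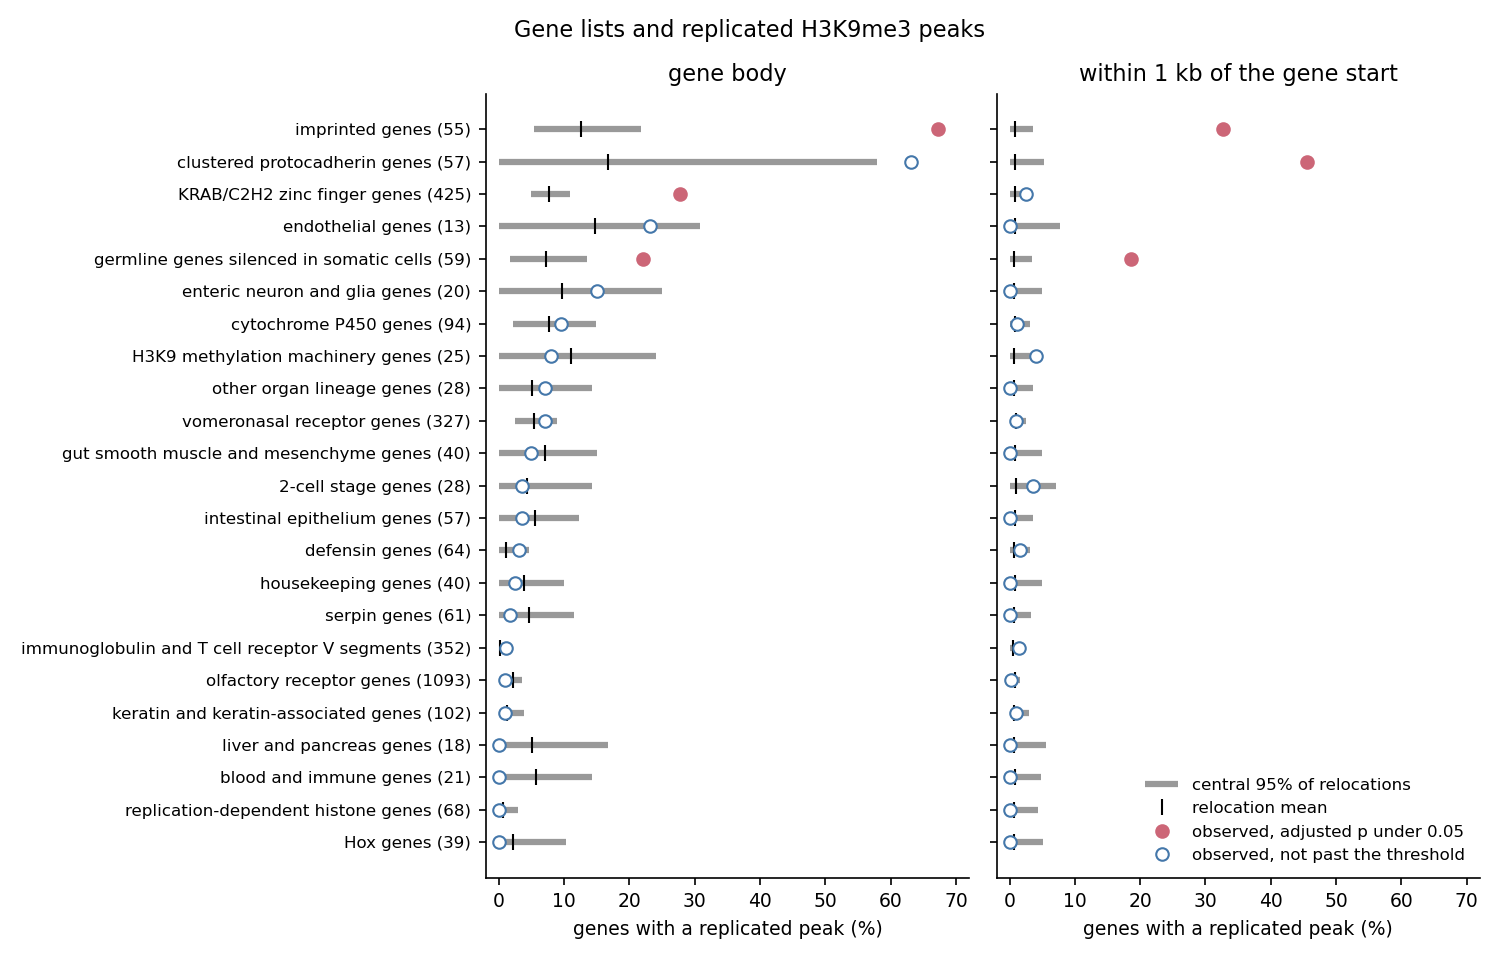
Points give the percent of genes in each of 23 lists (members in brackets) with a replicated peak in the gene body (left) or within 1 kb of the gene start (right). Grey bars show the central 95% of 10000 relocations and ticks their mean. In gene bodies the imprinted, zinc finger and germline lists pass the threshold, and at gene starts the imprinted, clustered protocadherin and germline lists do.

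The clustered protocadherins, cell adhesion proteins of neurons encoded in tandem arrays on chromosome 18, formed the domain with most peak bases. A run of 65 replicated peaks covering 49892 bp lay between 37654794 and 37777970, over the variable first exons of the gamma cluster, where replicate 1's own list had 116 peaks and replicate 2's own list 68. A replicated peak lay within 1 kb of the start of 26 of 57 clustered protocadherin genes, against a mean of 0.464 after relocation, a ratio of 56.1 (adjusted permutation p = 0.0031). Replicate 1's own list marked 37 starts (ratio 19.6) and replicate 2's own list 24 (ratio 47.3), and 21 of the 26 had a peak in both. The highest signal values at starts were those of Pcdhga10 (7.08), Pcdhga12 (6.54), Pcdhgb2 (5.70) and Pcdhgb4 (5.42). Pcdhga1 and Pcdhga3 also had a marked start, but replicate 2's own list had no peak there. Gene bodies were marked in 36 of 57, which did not pass the threshold (ratio 3.79, adjusted permutation p = 0.056), but the list passed in replicate 1's own list (53 bodies, ratio 1.93, adjusted permutation p = 0.0015) and in replicate 2's own list (39 bodies, ratio 3.30, adjusted permutation p = 0.038). The members overlap in the annotation, so single peaks count for many of them and relocated peaks either met many members or few.

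**Figure D4:**
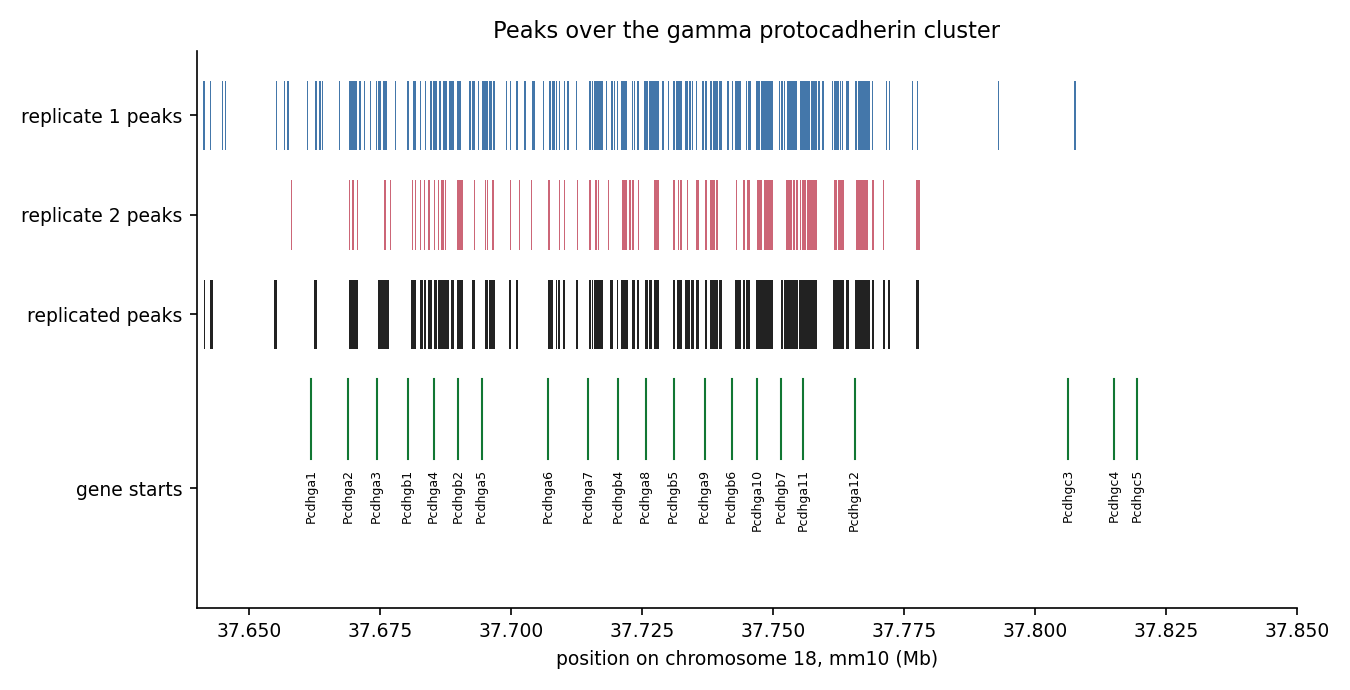
Map of the gamma protocadherin cluster on chromosome 18 of mm10, with peaks of both replicates' own lists and of the replicated list drawn to scale and the annotated gene starts as green lines. The joined domain of replicated peaks runs from 37654794 to 37777970, from before Pcdhga1 to beyond Pcdhga12, and no replicated peak overlaps the starts of Pcdhgc3, Pcdhgc4 and Pcdhgc5.

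For the same reason the 10 genes with most replicated-peak bases were all in this locus: Gm42416, Gm37013, Gm37388, Pcdhga1, Pcdhga2, Pcdhga3, Pcdhgb1, Pcdhga4, Pcdhgb2 and Pcdhga5. Gm42416 spans 36952741 to 37840200 and holds 102 peaks over 66304 bp, and Pcdhga5 holds 50 peaks over 37612 bp.

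Germline genes, which are silent in somatic tissue, were marked at their starts. A replicated peak lay within 1 kb of the start of 11 of 59 such genes, against 0.409 ± 0.641 after relocation, a ratio of 26.9 (adjusted permutation p = 0.0023). Replicate 1's own list marked 16 starts (ratio 8.58) and replicate 2's own list also 16 (ratio 31.7). In 9 of the 11 both replicates' own lists had a peak: Ddx4 (signal value 5.39), Dazl (5.12), Sycp2 (5.09), Stag3 (4.20), D1Pas1 (4.07), Fkbp6 (3.71), Nlrp5 (3.25), Zfp42 (3.25) and Rhox13 (3.25). These, and the other list members named only for their start, were chosen after their values were seen. Ddx4 and Dazl encode RNA-binding proteins of germ cells, and Sycp2 and Stag3 encode parts of the meiotic chromosome axis. Tdrd1 and Sycp1 also had a marked start, without a peak in replicate 1's own list. Gene bodies were marked in 13 of 59, a ratio of 3.04 (adjusted permutation p = 0.0061), with 24 in replicate 1's own list and 18 in replicate 2's. The body result largely counts the start peaks again, since all 11 genes with a marked start also had a marked body. Meioc, a regulator of meiosis, had 2 peaks in its body and none at its start. The body result did not pass the threshold in replicate 1's own list (adjusted permutation p = 0.088) or with peak midpoints inside the gene (adjusted permutation p = 0.090).

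The strongest peaks at gene starts included genes that are in none of these lists. Klf14, a single-exon transcription factor gene on chromosome 6 that is known to be imprinted though not in the fixed list, had the highest signal value in any start window, 9.69, in a peak from 30956969 to 30958688. Tcfl5, a transcription factor gene expressed in testis, followed on chromosome 2 (180642613 to 180644018) with 8.12. Boll, a germ cell gene related to Dazl, had 6.93 on chromosome 1 (55362616 to 55363366). Lrg1 on chromosome 17 and Gpr50 and Asmt on X each had a signal value of 6.04, the Lrg1 peak lying outside the gene body. Gm21887 on X had 6.64, with a −log10 p of 99.9, the highest in the replicated list. Gm26672, at 6.54, lies in the gamma protocadherin cluster. Across all 32455 genes, 314 had a marked start, against 238.7 ± 18.8 after relocation, a ratio of 1.32 (permutation p = 0.0006). This did not hold in replicate 1's own list (1113 starts, ratio 1.05, permutation p = 0.187) or the pooled list (ratio 1.08, permutation p = 0.076), and did in replicate 2's own list (373 starts, ratio 1.33, permutation p = 0.0002).

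Lists of genes of gut cell types, other organs and housekeeping functions went both ways around relocation, and none differed from it at an adjusted p under 0.05. Ratios in the replicates' own lists are given in brackets, replicate 1 first. In the intestinal epithelium list 2 of 57 genes had a peak in the body, a ratio of 0.626 (0.899 and 1.23): Lgr5, a stem cell receptor, and Apob, the apolipoprotein of chylomicrons. In the gut smooth muscle and mesenchyme list 2 of 40 did, Ano1 and Pdgfrb, a ratio of 0.702 (1.23 and 1.38). The enteric neuron and glia list had 3 of 20 (Gfra1, Nos1 and Chat), a ratio of 1.54 (1.26 and 1.63). The endothelial list had 3 of 13 (Erg, Flt1 and, without a peak in replicate 2's own list, Tie1), a ratio of 1.56 (1.32 and 0.809). Blood and immune genes had 0 of 21, against a relocation mean of 1.20, and liver and pancreas genes 0 of 18, against 0.923. Replicate 1's own list marked 3 blood genes (ratio 0.709) and 1 liver gene (ratio 0.280), and replicate 2's own list 0 of either. Other organ lineage genes had 2 of 28, Ttn, with 7 peaks, and Emx1, a ratio of 1.43 (1.78 and 1.10). Housekeeping genes had 1 of 40, Emc7, a ratio of 0.657 (0.468 and 1.05). In the replicated list no start was marked in any of these 8 lists, where relocation means were at most 0.442. Replicate 1's own list marked 3 housekeeping starts (ratio 2.13) and 3 other organ starts (ratio 3.18), neither past the threshold, and at most 1 in each other list. Replicate 2's own list marked at most 1 in each. These lists are short, so small shifts in gene bodies could be missed. With 1000 relocations, peaks planted in the bodies of 6 of the 59 germline genes were called in 16% of simulations. Tests of gene starts were not simulated.

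Other gene families in clusters did not differ from relocation at an adjusted p under 0.05 in the replicated list. Olfactory receptor genes had a peak in 11 of 1093 bodies, a ratio of 0.465 (adjusted permutation p = 0.197), with 84 in replicate 1's own list and 28 in replicate 2's, and in 3 starts. In replicate 1's own list their starts were marked less often than after relocation (18 starts, ratio 0.472, adjusted permutation p = 0.026). Vomeronasal receptor genes had 23 of 327, a ratio of 1.31. Hox genes had 0 of 39 and replication-dependent histone genes 0 of 68. Their relocation means were 0.853 and 0.430, so these 2 lists could not show a shortage of peaks. Cytochrome P450 genes had 9 of 94, keratin genes 1 of 102, serpin genes 1 of 61 and defensin genes 2 of 64. The zinc finger list did not pass the threshold at gene starts, with 11 of 425 marked (adjusted permutation p = 0.0575), but did within 5 kb of the start, with 41 marked (ratio 2.83, adjusted permutation p = 0.0023).

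Joined within 10 kb, the replicated peaks formed 6355 domains, of which 900 held more than 1 peak and 32 spanned at least 20 kb. After the gamma protocadherin cluster, the domain with most peak bases lay on chromosome 1 (88211588 to 88257954), with 34 peaks over Ugt1a genes, which encode glucuronosyltransferases, and Mroh2a. Its highest signal value, 2.95, was below the list median of 3.33. A neighbouring domain over Trpm8 (88282864 to 88310249) held 17 peaks. Domains without a protein coding gene, long noncoding RNA gene or V segment lay near the centromere of chromosome 4 (3049932 to 3091078, 20 peaks) and of chromosome 3 (3000186 to 3031663, 17 peaks), and on chromosome 4 at 121998440 to 122047830 (21 peaks). Other kinds of gene, such as pseudogenes, were not looked up. On chromosome 7, 21 peaks lay over Zfp329 and Zfp110 (12809551 to 12853488) and 19 over Zfp146 (30145349 to 30167771). Further domains covered Sfi1 and Drg1 on chromosome 11 (3184207 to 3200106, 10 peaks, highest signal value 2.91) and Smok2a and Smok2b on chromosome 17 (13199958 to 13239675, 14 peaks). Each of the 10 domains had peaks in both replicates' own lists. All 10 peaks of the Sfi1 and Drg1 domain, and others in the Ugt1a domain, had a signal value under 3 and a −log10 p of at least 10. Such peaks are candidates for high background, and domains were not joined again without them.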

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

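Peaks also lay in sequence that the comparisons with chance placement leave out. The replicated list holds 178 peaks on 15 of the 44 unplaced or unlocalised scaffolds of the assembly, which span 5.33 Mb in all. That is 33.4 peaks per Mb, 10.01 times the autosomal density. Replicate 1's own list had 287 peaks there, 3.25 times its autosomal density, replicate 2's own list 201, 8.80 times, and the pooled list 283, 4.19 times. The median signal value of the replicated scaffold peaks was 3.31, against 3.33 in the whole list, and their median −log10 p was 9.79, against 6.38. Some scaffold peaks had a signal value under 3 and a −log10 p of at least 10, and are candidates for high background. Most of those lay on JH584304, the scaffold with most replicated peaks (35). No gene list uses these scaffolds.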

How the results depend on the processing

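Added after seeing the data were the alternatives without high-background peaks and with peaks met by both replicates' own lists. Overlap between the replicates stayed above relocation under all alternatives run for it, with 22.8% to 47.6% of replicate 2 and 7.13% to 21.6% of replicate 1 peaks shared. The zinc finger and imprinted lists passed the threshold for gene bodies, and the imprinted, protocadherin and germline lists for gene starts, under every alternative. The number of lists past the threshold for gene bodies rose from 3 to 5 with the pooled list and to 8 with Fisher's exact test, which ignores gene length and clustering; of those 8 only 4 lay above the background and 4 below it, the olfactory (odds ratio 0.108), V segment, keratin and histone lists. With Fisher's exact test V segments turned from above to below the background (odds ratio 0.125). Intergenic share changed side: 54.7% with the pooled list, now above relocation, against 48.6% at q at or below 0.01, 48.3% at or above the median signal value, 47.0% with peaks met by both replicates and 46.8% as a share of bases, all then below it, and 51.0% to 55.4% with one replicate's own list, of which replicate 1's passed above relocation. Protocadherin bodies, short of the threshold in the main setting, passed in each replicate's own list, in the pooled list (ratio 2.08), with 5 kb on either side (4.37) and with Fisher's exact test, and zinc finger starts passed within 5 kb (2.83) and with Fisher's exact test (odds ratio 2.78). Introns no longer passed with peaks met by both replicates (39.6%, adjusted permutation p = 0.081). The X to autosome ratio was 0.287 in the pooled list, 0.139 at or above the median signal value and 0.270 to 0.444 with one replicate's list. Domains of more than 1 peak numbered 1395 joined within 50 kb, 598 within 1 kb, and 1214 to 6716 with one replicate's list. The cause of the intergenic, intron and X changes was not tested; joining distance and list length set the domain counts. No paired analysis was possible because both samples belong to one group. Depth is unknown, so a peak missing from a replicate's list does not show that the mark was absent.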

Other observations

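Genes of the H3K9 methylation machinery carried the mark in a few cases, though the list did not differ from relocation (2 of 25 bodies, ratio 0.724). Fam208a, which encodes TASOR of the HUSH silencing complex, had a start peak on chromosome 14 (27428067 to 27428712) with a signal value of 5.70, present in both replicates' own lists. Atf7ip, a partner of the methyltransferase Setdb1, had 4 peaks in its body, and Setdb1 had 1 that replicate 2's own list lacked. Of the 2-cell stage genes only Obox6 was marked, 1 of 28, with a start peak of signal value 4.18 in both replicates' lists. V segments had 4 marked bodies of 352, all of them Ighv segments on chromosome 12, and only Ighv7-4 had a peak in both replicates' own lists. The list did not pass the threshold in the replicated list (ratio 4.87, adjusted permutation p = 0.155) or in replicate 2's own list (2 bodies, ratio 2.24). It did in replicate 1's own list (ratio 3.95, adjusted permutation p = 0.0023) and in the pooled list (ratio 4.58, adjusted permutation p = 0.0037).

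Of the tests below, the one on signal values of the most significant peaks was chosen only after the result was seen. No biological explanation was tested for any of these patterns, since the design has 1 group.

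Most replicate 1 peaks lay outside the replicate 2 list. The weakest group of 5 was met at 20.8 times the relocation mean, above every relocation. Yet only 4.17% of its peaks were met, so this ratio cannot say how much of the missing overlap comes from weak calls. The share rose with significance but reached no more than 24.3% in the strongest group, so weak replicate 1 calls are unlikely to be the whole cause. List length alone would leave equal numbers of peaks mostly shared, but at most 22.8% were. This comparison kept every replicate 2 peak on assembled chromosomes, weak ones included, so length was not tested apart from weak calls. GC content differed by 1.05 percentage points between the medians of shared and unshared peaks. A difference in depth or enrichment between the libraries, or between the embryo pools, stays open and was not tested, and some weak calls may still be noise.

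Some of the most significant replicated peaks had low signal values, as at Gm26917 on chromosome 17 (39843034 to 39846792; signal value 2.78, −log10 p 99.3) and over Sfi1 and Drg1 on chromosome 11. High background at sequence that is collapsed or repeated in the assembly is a candidate explanation. Of the 100 most significant replicated peaks, 34% had a signal value below the list median, which lies between the bounds set for and against it. Neither repeats nor copy number were measured at these peaks, so this count could not tell high background apart from a true broad enrichment. Of the 100 peaks, 29 lay on scaffolds. Leaving out peaks of this kind took the peaks on assembled chromosomes from 8101 to 8056 and changed no gene list's side of the threshold; the rest of the 73 lay on scaffolds, which no list uses.

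Zinc finger genes carried peaks at the last exon. Exon length does not account for it, since the count was 16.8 times the mean of relocations that keep exon length and above their maximum of 19. Reads shared between paralogs would put peaks at repeated sequence. In the 83 marked last exons, 5.14% of 31-mers on average occurred more than once on the assembled chromosomes (SD 7.52, median 1.87%). The 31-mers were sampled every 5 bp, and another copy in the same exon also counted. The 336 unmarked ones had 18.8% (SD 29.7, median 3.03%, two-sided permutation p of the means = 6e-05). Last exons of other genes matched on GC content were marked at 0.0169 of the zinc finger rate, 7 of 2095, and 27 of 2095 when also matched on length. Dropping reads that map to several places would also leave repeated exons without peaks and fix this result in advance. Whether such reads were dropped is unknown, so the 5.14% speaks at most against false peaks at shared sequence.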
